A study of Mus musculus with 10 samples.

How the data were processed

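Gene expression was measured on single-colour microarrays in cells derived from A2lox.Meis1, a mouse embryonic stem cell line in which doxycycline switches on a Meis1 transgene. Meis1 encodes a homeodomain transcription factor that acts in blood formation and leukaemia. Per the labels, the cells grew as embryoid bodies until day 6 and were then plated at 100000 cells per ml on irradiated OP9 stromal cells carrying GFP, with blood cytokines. Doxycycline was added on day 6 at 500 ng per ml or left out, so cells had been exposed for 24 hours on day 7 and for 48 hours on day 8. GFP-negative cells were sorted by surface CD41, the integrin subunit encoded by Itga2b, an early marker of blood commitment that stays high on megakaryocytes. Day 7 gave a CD41- and a CD41+ fraction, and day 8 gave a CD41-, a CD41int and a CD41hi fraction. Total RNA (50 ng) was amplified with a NuGEN kit and labelled, per the labels' protocols.

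The deposited table holds log2 expression values, 1 per probe and array, made by RMA per the submitters' processing notes. RMA corrects the background, equalises the arrays and summarises the probes of a set. Its version, the software, the genome build and whether all arrays were normalised together are not given in the sources used here. The log2 scale of the deposited values was taken from RMA and from their range, 1.63 to 14.19. Such values compress differences near background, so folds of dim genes are understated. The table has 29674 probes and 10 arrays, with 0 columns not used and 0 pairs of identical columns. For arrays no read depth exists, and the precision stated here rests on their number and on the spread between them.

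Gene names came from the platform annotation, which can be old. Of the probes, 21780 carried 1 gene symbol, 1618 carried several and 6276 carried none. The last 2 kinds were not named. Of the probes with 1 symbol, 21689 were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, which changed 0 symbols. No coordinates were taken from it, because the array's build is not given, and it served for names and for which genes neighbour each other. Each of 19933 genes was read by its brightest probe, the one with the highest mean over the 10 arrays. For 996 genes more than 1 probe existed. Disagreements are stated for genes that ranked in a comparison, in that comparison. They were not looked for in Itga2b or in genes named only as members of a list. No filter on dim probes was applied.

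The 10 arrays form 5 pairs, each a doxycycline and an untreated array of the same fraction and day, and there are 4 cultures (2 days by 2 treatments). The pairing comes from the day and fraction in the labels; the replicate numbers 1 to 5 follow the order of the records and only name the arrays. In the 4 pairs other than that of day 7 CD41- cells, deviations from the group means correlated at r = 0.605 to 0.864 across genes within a pair. Between arrays of different pairs the highest value was 0.329. Fractions sorted from 1 culture are not independent cultures, and nothing in the labels says that a culture was repeated. The p-values therefore measure only the spread between these arrays, which may be technical. Each day and treatment is 1 culture, and no doxycycline-treated line without the transgene is among the samples. Differences between days cannot be told apart from differences between cultures, nor effects of Meis1 from those of doxycycline itself.

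Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes and Benjamini-Hochberg adjustment over all 19933 genes. A gene was called at an adjusted p under 0.05. The doxycycline effect was fitted with the 5 strata of fraction and day as a block. CD41-positive arrays (6) were set against CD41-negative arrays (4) with the culture as a block. The positive populations were pooled, so differences between CD41int and CD41hi cells add to the spread of this fit. CD41hi minus CD41int on day 8 was a contrast of a fit with the culture and 4 populations. Day 8 minus day 7 in CD41- cells was a contrast of the doxycycline fit. Interactions of doxycycline with CD41 and with day were added terms. Within a pair there is 1 array on each side and no test; differences of at least 2-fold were counted, and the median of each list was placed among those of 10000 random lists matched on mean expression.

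The groups, these fits, the rule for named genes, the alternatives and 22 gene lists were fixed before the data were examined. The lists cover erythroid, globin, heme synthesis, megakaryocyte, myeloid, mast cell and basophil, endothelial, haematopoietic regulator, Hox and TALE, and Meis1-associated genes. They also cover cell cycle, cyclin-dependent kinase inhibitor and apoptosis, glycolysis and hypoxia, ATF4 stress response, immediate early, and interferon genes. Markers of other cell types a fraction could hold were stroma and smooth muscle, cardiac, endoderm, neural, epithelial and pluripotency genes. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with at least 5 measured genes each. An estimated correlation and fry were alternatives. Several lists share genes: 10 of 30 haematopoietic regulators, 8 of 29 erythroid and 6 of 19 Meis1-associated genes are also in another list.

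The rule for named genes took, for the doxycycline effect and both CD41 comparisons, the 10 highest and 10 lowest log2 differences among called genes of the same sign in every pair. Remaining places went to the smallest limma p of the same sign, named as not past the threshold. For the day contrast and the interactions 5 places in each direction were taken, without the sign condition for the interactions. Predicted or unnamed genes were passed over. Meis1 and Itga2b were always named, and of each list up to 4 members with the smallest p, or a member used as an example. The text names a part of the genes that this rule gives on all 10 arrays and again on 9 arrays, chosen after their values were seen.

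The array of day 7 CD41- cells with doxycycline stood apart from the others, and every fit was repeated without it. Leaving out each array in turn was planned. Making the 9 arrays a full second set of fits, with the other alternatives on them, was chosen after seeing the data. Results are given on 10 arrays, on these 9 arrays or on both, and on the 9 arrays the doxycycline effect rests on 4 pairs. Other alternatives were centring on the median, a second quantile normalisation, genes above the median level, every probe on its own, an intensity trend with a robust fit, and array weights. An adjusted p of 0.10, an added 2-fold limit, fits without the block, a random culture block, and subsets of days, fractions or treatments were also run.

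The fits were tested on simulated values with known differences of log2 1 and 2 in 100 genes each, among 19933 genes. For the doxycycline effect 17% and 65% of these were called on 10 arrays, and 89% and 100% on 9. For CD41-positive against CD41-negative cells it was 22% and 70% on 10 arrays, and 67% and 95% on 9. For CD41hi against CD41int cells 0% were called on 10 arrays, and 39% and 83% on 9. The day contrast recovered 0% on 10 arrays, and 48% and 92% on 9. The interaction with CD41 recovered 0% in either case, and that with day 0%, except 42% at log2 2 on 9 arrays. The simulated noise was independent between genes and arrays, with the same spread for a gene on every array. In the data 1 array stands apart and arrays share cultures, so these shares need not hold for the data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.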

Results

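The data are 10 arrays of sorted mouse cells, 5 from untreated cultures and 5 from cultures given doxycycline, to which the line's Meis1 transgene is built to respond, matched in 5 pairs by day and CD41 fraction. The title of the series states its purpose as finding genes that Meis1 acts on. Of the 10 arrays, 9 correlated with one another at r = 0.963 to 0.994 across all probes, with standard deviations of 2.13 to 2.20 log2 units. The array of day 7 CD41- cells with doxycycline correlated at r = 0.443 to 0.476 with the other 9 and had a standard deviation of 1.20. On it, transcripts that are abundant elsewhere were low: Actb, the cytoskeletal actin, read 7.82 against 12.62 to 13.04 on the other arrays, and the glycolytic enzyme gene Pgk1 read 6.82 against 12.03 to 12.17. Its pair held 6373 genes higher and 4901 lower by at least 2-fold, against at most 24 higher and 55 lower in any other pair. The number of genes called in each comparison is therefore given on all 10 arrays and on the 9 others. Counts within lists are given on either set or on both, as stated.

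**Figure D1:**
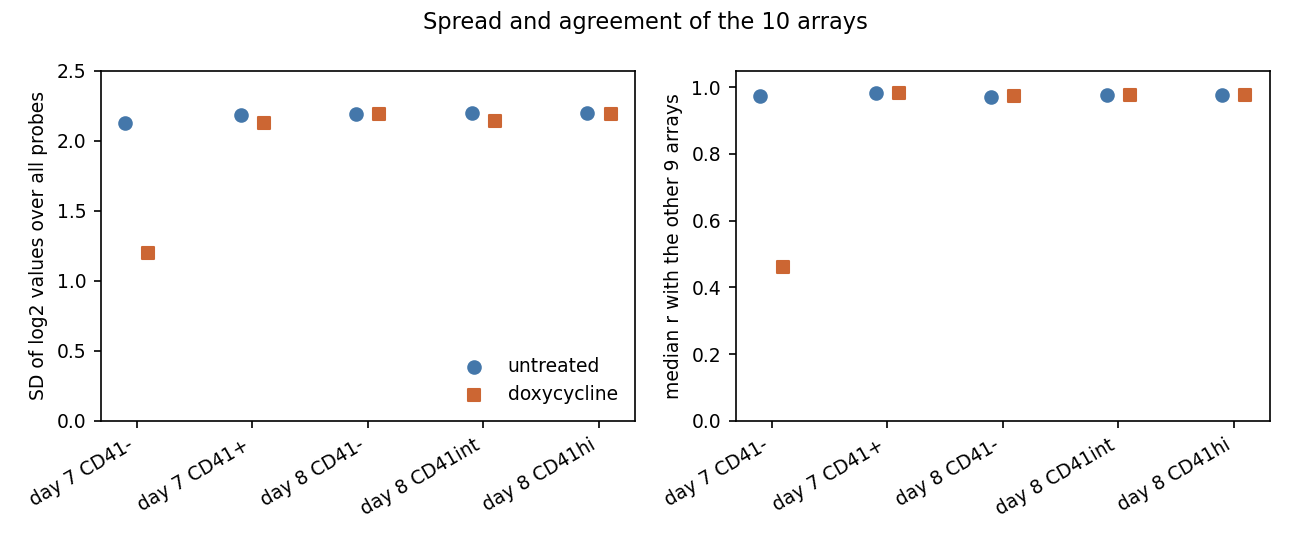
Standard deviation of the log2 values over all probes (left) and median correlation with the other 9 arrays across probes (right) for each array, by day and CD41 fraction, with 1 point per array. The doxycycline array of day 7 CD41- cells lies at 1.20 and 0.460, and the other 9 arrays lie at 2.13 to 2.20 and above 0.97.

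Meis1 and Itga2b were read on every array first. Meis1 was higher with doxycycline in 4 of 5 pairs, at 8.36 against 7.63 in day 7 CD41+ cells, 8.50 against 7.92 in day 8 CD41- cells, 8.55 against 7.52 in CD41int cells and 9.78 against 8.96 in CD41hi cells. In the fifth pair the array that stands apart read 6.67 against 7.77. The mean Meis1 difference was 0.41 ± 0.33 (log2, SE, 5 pairs; limma adjusted p = 0.565), and on the 9 arrays it was 0.79 ± 0.10 (4 pairs; adjusted p = 0.0715), a 1.73-fold higher level that did not pass the threshold. Whether the Meis1 probe reads the transgene is not given in the sources used here. Untreated Meis1 was also highest in CD41hi cells. Itga2b, the gene of the sort marker, followed the gates on day 8, with untreated levels of 5.51 in CD41-, 6.23 in CD41int and 8.31 in CD41hi cells, and on day 7 it read 5.76 in CD41- and 7.12 in CD41+ cells. With doxycycline Itga2b differed by 0.39 ± 0.26 on 10 arrays (adjusted p = 0.565) and by 0.15 ± 0.14 on 9 (adjusted p = 0.791).

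**Figure D2:**
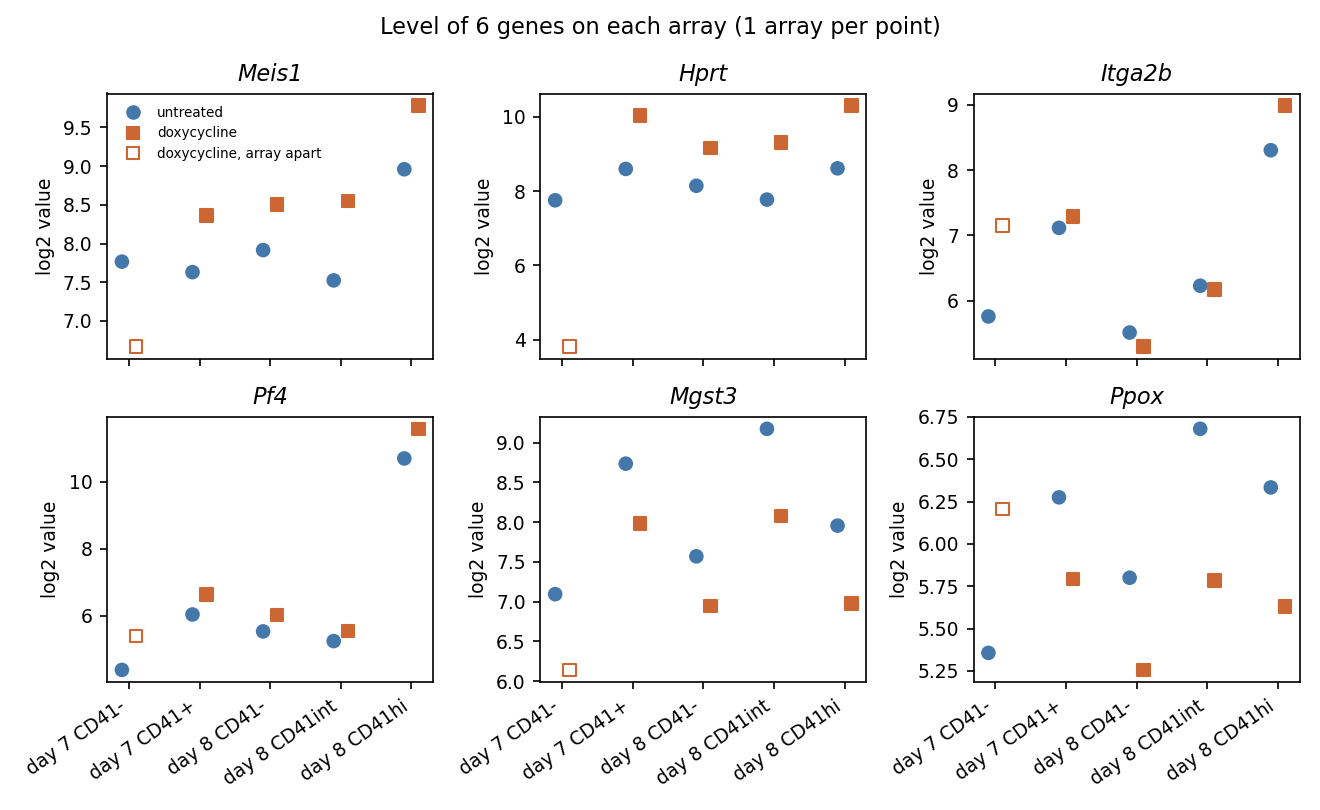
Log2 level of Meis1, Hprt, Itga2b, Pf4, Mgst3 and Ppox on each array by day and CD41 fraction, 1 array per point, untreated as circles and doxycycline as squares, with a hollow square for the array that stands apart. Without that array Hprt read 9.16 to 10.30 with doxycycline and 7.75 to 8.61 without, and Meis1 was higher with doxycycline in 4 of 4 pairs.

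The comparison of doxycycline with untreated cells asks which genes differed after the inducer was given. On the 9 arrays Hprt, the purine salvage enzyme, rose by 1.42 ± 0.11 log2 units (SE, 4 pairs; 2.67-fold; limma adjusted p = 0.00619), higher in 4 of 4 pairs. Genes next in order, none past the threshold, were higher or lower in all 4 pairs. The rule that picked most of them requires the same sign in every pair, so this agreement adds no support. Higher were Slc35d3, a transporter acting in platelet dense granules, by 0.86 ± 0.11 (adjusted p = 0.072), the Wnt regulator Dact1 by 0.68 (0.152) and the platelet chemokine Pf4 by 0.57 ± 0.10 (adjusted p = 0.307). Both subunits of soluble guanylate cyclase were also higher, Gucy1b1 by 0.69 (adjusted p = 0.28) and Gucy1a1 by 0.53 (adjusted p = 0.404). Lower were Mgst3, a microsomal glutathione transferase, at -0.86 ± 0.10 (adjusted p = 0.0715), and Ppox, an enzyme of heme synthesis, at -0.66 (adjusted p = 0.152). The myeloid adaptor Tyrobp (-0.61) and the chemokine Ccl9 (-0.62) were lower as well (both adjusted p = 0.152). So were the steroid enzyme gene Hsd3b6 (-0.82, adjusted p = 0.165), the carbonic anhydrase Car1 (-0.62, 0.246), the lectin Clec4n (-0.92, 0.28) and the mitochondrial iron carrier Slc25a37 (-0.74, 0.307). Others were Tdo2 (0.59), Cldn13 (0.50), Ptn (0.55), Lyve1 (0.44) and Tbx5 (0.45) above untreated, and Ccnb1ip1 (-0.58), Upp1 (-0.62) and Shmt2 (-0.48) below. Their adjusted p ranged from 0.165 to 0.399.

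On all 10 arrays limma called 0 genes for doxycycline, with 214 at an unadjusted p under 0.05, and on the 9 arrays it called 1, with 1785. Chance alone gives 997 on average. Hprt was 0.35 ± 0.85 on 10 arrays (adjusted p = 0.79), reading 3.81 against 7.75 in the pair of the array that stands apart. Mgst3 was lower in 5 of 5 pairs, as the rule for named genes requires, at -0.88 ± 0.15, with an adjusted p of 0.565. The call of Hprt on the 9 arrays was lost when the pair of day 7 CD41+, CD41int or CD41hi cells was also left out, and in the fit without the pairing.

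Among the 22 lists, genes of red cells were lower with doxycycline and genes of megakaryocytes, the platelet precursors, were higher on the 9 arrays. In the heme synthesis list 11 of 11 genes were lower, with a median of -0.37 (camera adjusted p = 1.66e-10, and adjusted p = 0.242 with an estimated correlation). In that list 0 genes passed over all genes and 7 fell when adjusted over the list alone, examples being Ppox and Urod (-0.44). In the erythroid list 25 of 29 genes were lower, median -0.24 (adjusted p = 5.95e-11, and adjusted p = 0.297 with an estimated correlation). None passed over all genes, and 11 fell and 1 rose adjusted over the list alone. Kel, a blood group antigen, was at -0.89 (0.307 over all genes), Mgst3 at -0.86 and Slc25a37 at -0.74, while the claudin Cldn13 was at 0.50. In the globin list 5 of 6 genes were lower, median -0.38 (adjusted p = 0.0002, and adjusted p = 0.297 with an estimated correlation), and 3 fell adjusted over the list alone. Hbq1b was at -0.71, and 3 of the 6 globins are also in the erythroid list. In the megakaryocyte list 26 of 32 genes were higher, median 0.17 (adjusted p = 5.41e-07, and adjusted p = 0.297 with an estimated correlation), and 5 rose adjusted over the list alone, with Pf4, Gucy1b1 and Gucy1a1 as examples. The cardiac list, with 19 of 23 genes higher, had a median of 0.17 (adjusted p = 0.0002, and adjusted p = 0.297 with an estimated correlation). In it 2 genes rose adjusted over the list alone. Its examples were the heart troponin Tnnt2 at 1.17 ± 0.24 (0.37) and the transcription factor Tbx5 at 0.45.

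Other lists past the camera threshold on the 9 arrays were lower by smaller medians. Glycolysis and hypoxia genes were at -0.13 (22 of 26 lower, adjusted p = 0.000225), immediate early genes at -0.12 (15 of 20, 0.000621), ATF4 stress response genes at -0.07 (19 of 23, 0.00224) and haematopoietic regulators at -0.06 (19 of 30, 0.0155). For these 4 lists the adjusted p = 0.297 with an estimated correlation. Myeloid genes were at -0.08 (24 of 37 lower, adjusted p = 0.00447, and adjusted p = 0.347 with an estimated correlation), with Tyrobp and Cd14 (-0.54) among the 5 that fell adjusted over the list alone. Interferon genes were at -0.09 (14 of 17 lower, adjusted p = 0.00797, and adjusted p = 0.558 with an estimated correlation). Adjusted over the list alone, 3 immediate early, 2 ATF4, 3 interferon, 0 glycolysis and 0 regulator genes fell, the regulator Myb being at -0.42. The Meis1-associated list had a median of 0.06 and a mean of -0.02, with camera pointing down (adjusted p = 0.837). In it 2 genes rose and 4 fell adjusted over the list alone, Pf4 at 0.57, and Ccl3 at -0.68 and Myb among the lower ones. The remaining lists did not pass: stroma 0.09 (0.0769), pluripotency 0.10, epithelial 0.08 and endoderm 0.06 (each 0.0918), cell cycle -0.03 (0.114), endothelial -0.06 (0.131), kinase inhibitors and apoptosis -0.08 (0.237), Hox and TALE 0.03 (0.304), neural 0.00 (0.344) and mast cell 0.07 (0.421).

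Of the 22 lists 11 passed camera on the 9 arrays (2 higher, 9 lower), 0 passed with an estimated correlation and 0 by fry. On all 10 arrays 8 lists passed and again 0 with an estimated correlation or by fry. These 8 included heme synthesis (median -0.29, adjusted p = 0.000771, and adjusted p = 0.382 with an estimated correlation) and erythroid genes (-0.13, adjusted p = 0.00384, and adjusted p = 0.506 with an estimated correlation). Megakaryocyte genes were at 0.30 (adjusted p = 0.00102, and adjusted p = 0.502 with an estimated correlation). Cell cycle genes were at -0.63 (adjusted p = 4.85e-08, and adjusted p = 0.506 with an estimated correlation), while on the 9 arrays their median was -0.03. The others were glycolysis at -0.36 (adjusted p = 1.05e-05, and adjusted p = 0.44 with an estimated correlation), immediate early at -0.17 (0.00384, 0.44), kinase inhibitors at -0.27 (0.00897, 0.506) and ATF4 at -0.16 (0.0348, 0.44), the second p of each again with an estimated correlation.

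Pair by pair, erythroid and megakaryocyte genes lay apart from random lists in the CD41-positive fractions. The erythroid median was -0.27 in day 7 CD41+ cells, -0.26 in CD41int and -0.57 in CD41hi cells, each below all 10000 random lists, and -0.05 in day 8 CD41- cells, at percentile 45.4. In untreated day 8 CD41- cells the mean level of these genes was 6.25, near the median of 5.97 over all genes. It was 7.74 to 7.85 in the untreated positive fractions, so a fall is harder to see in CD41- cells. The heme synthesis median was -0.32, -0.50 and -0.67 in those positive fractions and -0.21 in day 8 CD41- cells (percentile 0.81). The globin median was -0.28 (percentile 0.1), -0.13 (15.4, not apart from random lists) and -0.68 in them and -0.49 in day 8 CD41- cells, the last pair of values below all 10000 random lists. The megakaryocyte median was 0.20 in day 7 CD41+, 0.12 in CD41int and 0.44 in CD41hi cells (percentiles 99.99, 99.8 and 100) and 0.01 in day 8 CD41- cells (90.3). Other lists, markers of other cell types among them, also lay apart from random lists in these pairs. In CD41int cells epithelial genes were at 0.32 (percentile 99.99), pluripotency genes at 0.30 (99.96), stroma genes at 0.21 (100), cardiac genes at 0.21 (99.95) and cell cycle genes at -0.21 (0.08). In day 7 CD41+ cells epithelial genes were at 0.20 (99.61), cardiac genes at 0.18 (99.78), interferon genes at 0.16 (99.59) and stroma genes at 0.11 (99.51). In CD41hi cells endothelial genes were at -0.14 (0.02) and interferon genes at -0.24 (0.01), myeloid genes were at -0.26, below all 10000, and epithelial genes at 0.04 (73.9). Cell cycle genes were at 0.08 (99.29) in CD41hi cells, opposite to CD41int cells. The day 8 CD41- pair had shifts of its own, with immediate early genes at -0.25 and glycolysis and hypoxia genes at -0.22, both below all 10000, interferon genes at -0.22 (0.23), epithelial genes at -0.21 (0.64), pluripotency genes at -0.21 (0.52) and Meis1-associated genes at -0.20 (0.3). Only Hprt differed by at least 2-fold one way in all 4 pairs, and 0 genes did so in all 5. With 1 array on each side these pair values have no replicate check. The random lists were drawn gene by gene and matched only on mean expression, so they lack the correlation between genes of a list. Their percentiles are therefore too extreme to read as a test, and no list passed for doxycycline with an estimated correlation.

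**Figure D3:**
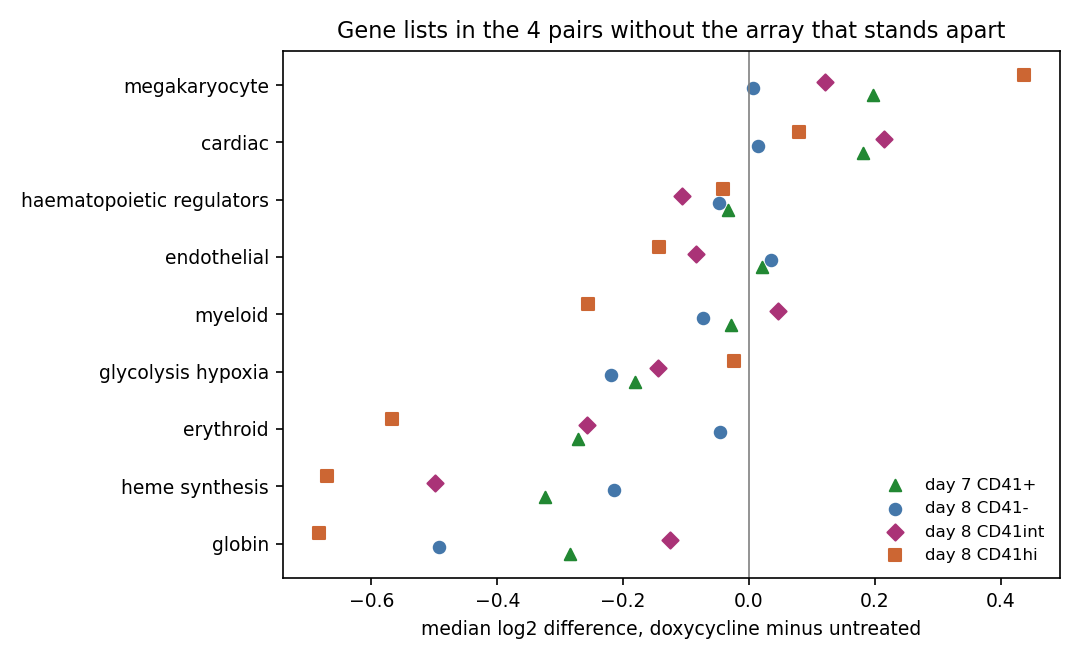
Median log2 difference, doxycycline minus untreated, of 9 gene lists in the 4 pairs without the array that stands apart, 1 point per pair. The heme synthesis medians lie between -0.67 and -0.21, and the megakaryocyte medians between 0.01 and 0.44.

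CD41-positive cells were set against CD41-negative cells of the same culture to see how the sorted fractions differ. On 10 arrays the erythroid, heme synthesis and globin lists were higher in the positive fractions, each with adjusted p = 0.0308 with an estimated correlation, and with 0.1 on the 9 arrays. Klhl6 rose by 3.29 ± 0.16 (SE, 10 arrays; limma adjusted p = 0.00106), Prkar2b, a regulatory subunit of protein kinase A, by 4.06 ± 0.42 (0.0134) and the embryonic globin Hbb-bh1 by 3.68 ± 0.63 (0.0466). Hba-x (3.44) and Hbb-y (3.23), also embryonic globins, rose with it. So did Nfe2 (3.26), a transcription factor held in the erythroid list, and the ammonium channel relative Rhag (3.02). Kdr, the VEGF receptor, rose by 3.16 ± 0.34, Cd34 by 3.06 ± 0.33, Myct1 by 3.13, the endothelial and blood factor Fli1 by 3.05 and Gimap6 by 3.18. Receptor and matrix genes Csf2rb (3.34), Lilr4b (3.63), Tyrobp (2.76) and Hapln1 (3.65) rose too. Lower were Fbxo15 at -3.69, L1td1 at -3.48 ± 0.36, Dppa3 at -3.22, Zfp42, a marker of undifferentiated cells, at -3.20 ± 0.25 and Rhox9 at -3.05, together with the epithelial adhesion genes Epcam (-2.69) and Cdh3 (-2.38) and the meiotic gene Sycp3 (-2.50). Not past the threshold on 10 arrays were Tdgf1 (-3.80, 0.0869), Dppa5a (-3.74, 0.0683), Pou5f1 (-3.12, 0.0633), Apela (-3.53, 0.16) and Spink1 (-3.19, 0.176). All 5 passed on the 9 arrays, Pou5f1 at -3.91 (0.00104) and Tdgf1 at -4.92 (0.00114). The other gene values above are on 10 arrays, with the array that stands apart as 1 of the 4 CD41-negative arrays. Without it Prkar2b was at 3.58 and Hapln1 at 3.51. Larger without it were Rhag (3.45), Csf2rb (3.55), Lilr4b (3.75), Kdr (3.30), Cd34 (3.29), Myct1 (3.33) and Tyrobp (3.28). None of these globins was among the 10 highest genes on the 9 arrays, which ended at 3.28. Meis1 was at 0.62 (0.522) and Itga2b at 1.48 ± 0.66 (0.441), and on the 9 arrays at 0.32 (0.72) and 1.84 ± 0.70 (0.19). This fit pools CD41int and CD41hi cells, and the difference of a gene between them enters its spread.

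By list, on 10 arrays, 27 of 29 erythroid genes were higher (median 1.20, camera adjusted p = 1.1e-20). Of these 8 rose over all genes and 21 adjusted over the list alone, Alas2, the first enzyme of red cell heme synthesis, by 2.15. Heme synthesis genes were higher in 11 of 11 (1.06, 2.76e-09) and globins in 6 of 6 (2.19, 2.7e-06). For these 3 lists the adjusted p = 0.0308 with an estimated correlation. Haematopoietic regulators were at 0.76 (26 of 30 higher, 6 rose and 13 adjusted over the list alone, adjusted p = 9.25e-14, and adjusted p = 0.0505 with an estimated correlation). Endothelial genes were at 0.88 (29 of 34 higher, 5 rose and 14 adjusted over the list alone, 4.45e-13, and adjusted p = 0.222 with an estimated correlation). Megakaryocyte genes were at 1.004 (29 of 32 higher, 0 rose either way, 2.24e-07, and adjusted p = 0.377 with an estimated correlation). That value averages unlike fractions. Relative to the mean of the 9 arrays, the megakaryocyte median in untreated day 8 cells was 1.485 in CD41hi, -0.51 in CD41int and -0.69 in CD41- cells. The gap between CD41hi and CD41int cells widens the spread, so the lack of called genes is no sign of an absent difference. Pluripotency genes were lower in 15 of 15 (-2.12, 6 fell and 13 adjusted over the list alone, 1.22e-15, and adjusted p = 0.0639 with an estimated correlation). Epithelial genes were lower in 13 of 13 (-1.72, 2 fell and 10 adjusted over the list alone, 2.76e-09, and adjusted p = 0.125 with an estimated correlation). Stroma genes were lower in 25 of 25 (-0.79, 0 fell and 16 adjusted over the list alone, 1.22e-09, and adjusted p = 0.222 with an estimated correlation), with Pdgfra at -2.30 (0.0541). Cardiac genes were at -0.58 (20 of 23 lower, 1 fell and 7 adjusted over the list alone, 5.27e-06, and adjusted p = 0.0938 with an estimated correlation), with Myl7 at -0.79. Endoderm genes were at -0.32 (19 of 20 lower, 0 fell and 6 adjusted over the list alone, 0.000112, and adjusted p = 0.222 with an estimated correlation), with Ttr at -1.35. Sox2, in both the neural and the pluripotency list, was at -1.95. These list values include the array that stands apart as 1 of the 4 CD41-negative arrays. Relative to the mean of the 9 arrays, the epithelial median was 0.01 on it, against 1.44 to 1.75 on the other CD41- arrays. The endoderm median was 0.87 on it, against 0.06 to 0.15, and the globin median -2.46, against -1.47 to -0.86. List medians and counts without it are not given for this comparison. No list passed with an estimated correlation on the 9 arrays, the smallest adjusted p being 0.1.

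In this comparison limma called 190 genes on 10 arrays, 80 higher and 110 lower, and 1470 on the 9 arrays, 462 higher and 1008 lower. All 190 were among the 1470, in the same direction. On all 10 arrays, leaving out 1 array gave between 1 and 1470 calls, and on the 9 arrays between 117 (without untreated day 8 CD41-) and 1860. Of the 190 called genes 42.1% were higher, and after centring each array on its median 53.8% of 158 were.

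Within the positive cells of day 8, CD41hi was set against CD41int. The platelet chemokine Pf4 rose by 5.74 ± 0.27 (SE, 10 arrays, 2 pairs; limma adjusted p = 0.0218), a 53.6-fold higher level. The platelet glycoprotein Gp5 (4.37), Rgs18 (4.22), the integrin partner of CD41 Itgb3 (3.99) and the thrombin receptor family member F2rl2 (3.80) rose with it. Adh6b (-4.47) and the ceramidase Acer2 (-3.50) fell. A second, dimmer probe gave -0.82 for Adh6b and -0.24 for Acer2. On the 9 arrays, where the differences are equal and the spread is smaller, more genes rose, among them the platelet tubulin Tubb1 (2.57), Cd226 (3.35), Plek (3.65), Slamf1 (3.41), Btk (3.40) and Prkca (3.13). Meis1 rose by 1.34 ± 0.14 (adjusted p = 0.000343; 0.684 on 10 arrays) and Itga2b by 2.45 ± 0.20 (0.000104; 0.127 on 10 arrays). Genes that fell on the 9 arrays included the endothelial sialomucin Emcn (-3.45), Ptprb (-2.44), the angiopoietin receptor Tek (-2.47), Adgrf5 (-3.76), Edn1 (-3.00), Ednrb (-2.83), the matrix protein Postn (-3.67), Klhl4 (-4.35), Peg3 (-3.87), Hmcn1 (-2.63) and Prex2 (-2.98). Mecom (-2.91) and Dab2 (-3.24) fell by their brightest probes, while a dimmer probe gave -0.30 and 0.00. The other probes of Hmcn1 ranged from -4.29 to -0.29.

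In the megakaryocyte list 31 of 32 genes were higher in CD41hi cells, median 2.22 (10 arrays, camera adjusted p = 2.82e-58, and adjusted p = 0.105 with an estimated correlation). Of these 5 rose over all genes and 27 adjusted over the list alone; on the 9 arrays 27 rose over all genes (8.66e-33, and adjusted p = 0.329 with an estimated correlation). In the endothelial list 30 of 34 genes were lower, median -1.20 (2.76e-29, and adjusted p = 0.105 with an estimated correlation), 19 of which fell adjusted over the list alone, and 24 fell over all genes on the 9 arrays. Stroma genes were at -0.60 (23 of 25 lower, 1.74e-11, and adjusted p = 0.194 with an estimated correlation), with 16 falling on the 9 arrays, Acta2 at -2.74. Interferon genes were at -0.48 (16 of 17 lower, 6.9e-11, and adjusted p = 0.105 with an estimated correlation), with 9 falling on the 9 arrays, Ifit3 at -2.18. Haematopoietic regulators were at 0.55 (22 of 30 higher, 2.27e-05, and adjusted p = 0.194 with an estimated correlation). Of them 14 rose and 2 fell on the 9 arrays, Runx1 at 2.27. Myeloid genes were at 0.38 (30 of 37 higher, 2.78e-06, and adjusted p = 0.5 with an estimated correlation), with 15 rising and 1 falling on the 9 arrays, Laptm5 at 1.88. Hox and TALE genes were at -0.12 (28 of 35 lower, 3.3e-06, and adjusted p = 0.284 with an estimated correlation), with 8 falling on the 9 arrays, the Meis1 relative Meis2 at -2.91. Adjusted over the list alone on the 9 arrays, 18 stroma, 12 interferon and 9 Hox and TALE genes fell, and 18 regulator and 17 myeloid genes rose. Erythroid genes were at -0.29 (20 of 29 lower, 0.021, and adjusted p = 0.5 with an estimated correlation), and on the 9 arrays 3 rose and 6 fell over all genes (0.0354, and adjusted p = 0.508 with an estimated correlation), 3 and 9 adjusted over the list alone. Epithelial genes (-0.73, 0.000151), pluripotency genes (-0.32, 0.00165), cardiac genes (-0.11, 0.00175) and neural genes (-0.12, 0.0115) were lower, with adjusted p = 0.376, 0.469, 0.194 and 0.457 with an estimated correlation. Cell cycle genes (0.24, 0.0232), ATF4 stress response genes (0.21, 0.000163) and Meis1-associated genes (0.25, 0.000196) were higher, with adjusted p = 0.693, 0.105 and 0.105 with an estimated correlation. Globin genes (-0.15, adjusted p = 0.605) and heme synthesis genes (0.04, 0.32) did not pass.

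Limma called 7 genes between CD41hi and CD41int cells on 10 arrays, 5 higher and 2 lower, and 2477 on the 9 arrays, 1110 higher and 1367 lower, including all 7 in the same direction. Leaving out any of the 6 day 8 arrays, or a second quantile normalisation, gave 0 in place of the 7, Pf4 included, and on the 9 arrays single arrays left out gave 1285 (without doxycycline CD41int) to 3177. Only 2 pairs of arrays hold this contrast.

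**Figure D4:**
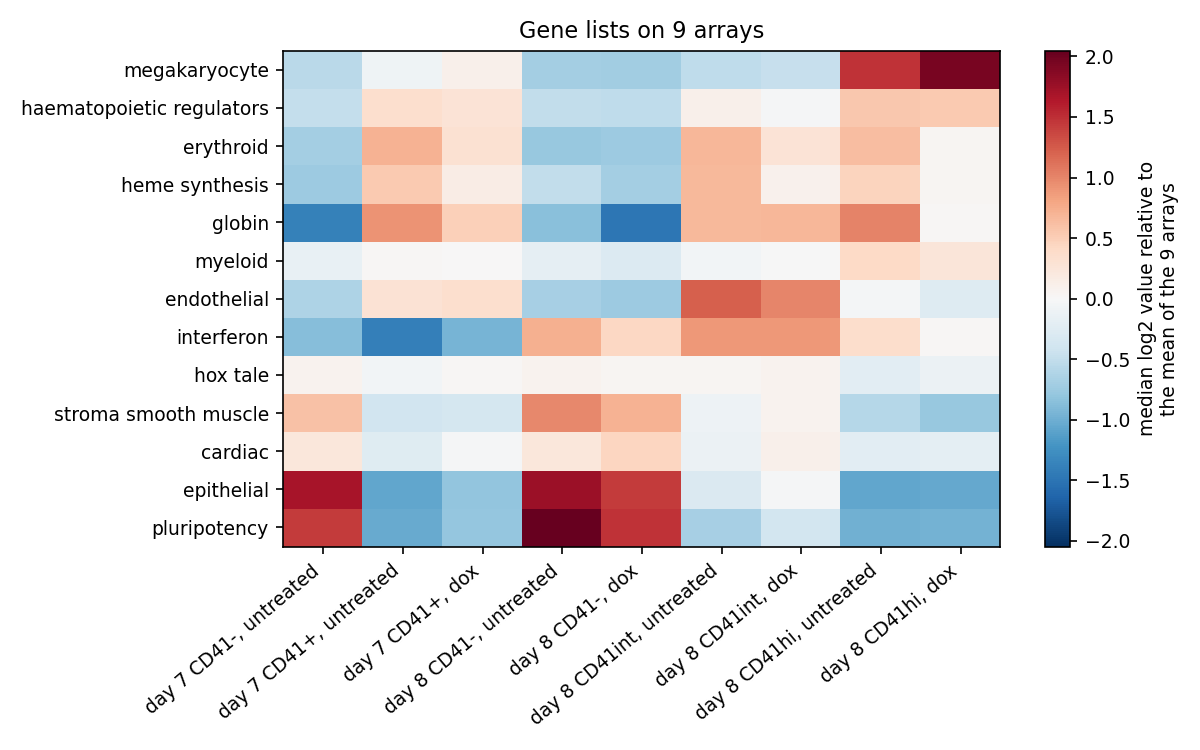
Median log2 level of 13 gene lists on 9 arrays, each gene taken relative to its mean over those arrays, with arrays in columns and lists in lines; red is above and blue below that mean. Megakaryocyte genes are highest in the CD41hi arrays, and pluripotency and epithelial genes in the CD41- arrays.

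Day 8 was set against day 7 in CD41- cells, the gate used on both days. On all 10 arrays the interferon-induced gene Ifit3b rose by 3.94 ± 0.27, Ifit1 by 3.79 ± 0.25 and Rtp4 by 3.34 ± 0.24 (SE, 2 arrays a day; limma adjusted p = 0.0256 each). Ifit3 rose by 4.35 ± 0.24 on the 9 arrays, a 20.4-fold higher level, with Ifit3b (4.03), Ifit1 (3.98), Rtp4 (3.39), Usp18 (3.38) and Trim30a (3.25). In the interferon list 14 of 17 genes were higher on 10 arrays, median 1.31 (camera adjusted p = 7.93e-09, and adjusted p = 0.541 with an estimated correlation), 1 rising over all genes and 10 adjusted over the list alone. Without the array that stands apart 16 of 17 were higher, median 1.44 (6.89e-28, and adjusted p = 0.455 with an estimated correlation), 11 rising over all genes and 13 adjusted over the list alone. By fry the list passed in both, with adjusted p = 0.0126 and 0.0237. Lower on the 9 arrays were the muscle genes Actc1 (-1.49, adjusted p = 0.0189) and Cnn1 (-1.43, 0.00676), the neuronal tubulin Tubb3 (-1.33, 0.0378), Kif5c (-1.16, 0.032) and Ssxb10 (-1.34, 0.0351). On 10 arrays Actc1, Cnn1 and Tubb3 were at 0.96, 0.28 and 0.53, the opposite sign. Besides the interferon list, others passed camera on 10 arrays, epithelial and myeloid genes among them. On the 9 arrays the medians of these lists were -0.04 and -0.06, with the direction by camera reversed. Limma called 3 genes on 10 arrays and 100 on the 9 arrays, 83 higher and 17 lower, including those 3. On 10 arrays 0 were called with array weights, with a second quantile normalisation or without any 1 array outside the day 7 CD41- pair, and 17004 without the untreated array of that pair, which leaves the array that stands apart as day 7. Each day is a separate culture, and on the 9 arrays day 7 CD41- cells are 1 untreated array, assumed to vary like the others.

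Whether the doxycycline difference itself differs between CD41-positive and CD41-negative cells, or between day 8 and day 7, was tested as an interaction. By limma 0 genes passed for CD41 on 10 arrays, with 120 at an unadjusted p under 0.05, and 0 on the 9 arrays, with 976. For day, 0 genes passed on 10 arrays (439) and 0 on the 9 arrays (1180). The genes with the smallest p included Rhag for CD41, at -1.70 ± 0.21 on the 9 arrays (adjusted p = 0.467; -2.17 on 10), and Plac8, at 3.61 on 10 arrays (0.635) and 2.74 on the 9 (0.976). For day they included Dcpp2 at -1.80 (0.457) and Cyp3a44 at -1.77 (0.594) on the 9 arrays. By camera on the 9 arrays the doxycycline difference of erythroid genes was lower in CD41-positive than in CD41-negative cells by a median of -0.30 (adjusted p = 4.77e-07), with 20 of 29 genes lower and 6 falling adjusted over the list alone. That of epithelial genes was higher by 0.50 in 13 of 13 genes (adjusted p = 4.08e-05), with 0 rising adjusted over the list alone. For both the adjusted p = 0.49 with an estimated correlation. The CD41-negative side of the 9 arrays is the single day 8 pair, and their day 7 side is the single CD41+ pair. Erythroid genes had a mean level of 6.25 in untreated day 8 CD41- cells, against 7.74 to 7.85 in the untreated positive fractions. Since values near background are compressed, a smaller fall in CD41- cells may reflect this lower level, and the interaction cannot separate the 2.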

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

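The tests that weigh explanations for the 3 patterns here were chosen only after the results were seen, as were the fits on 9 arrays. Counts over other assignments of the arrays were planned, but on the 9 arrays they rest on that later choice of arrays.

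Within the 5 doxycycline arrays, the array of day 7 CD41- cells lay far from the other 4. Its gap to the nearest array took up 0.936 of the whole range for the standard deviation of the log2 values, 0.979 for the median correlation with the other arrays and 0.793 for the median log2 value. Within the 5 untreated arrays, day 7 CD41- cells lay apart by 0.711 in the standard deviation, and CD41hi cells lay apart by 0.727 in the level of Meis1, being the highest. Over the 4 pairs, the doxycycline difference of Hsd3b6 lay apart by 0.948 in CD41hi cells, at -1.33 against -0.66 to -0.63. Of 63 sets tested in this way 6 passed, where chance gives about 3.15.

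The first pattern is the doxycycline array of day 7 CD41- cells. Its highest correlation with any other array, 0.476, goes against a swap within the series, and its highest rank correlation, 0.456 against 0.986 to 0.990 on the others, goes against a separate normalisation as the whole cause, as rescaling would largely keep the order of genes. A response of these cells to doxycycline goes against the median of the 100 brightest genes, which lay at -4.97 from the untreated partner, against -0.08 to 0.00 in the other pairs. A weak or degraded signal stays open, since across genes its deviations from the mean of the other 9 arrays followed those of its partner at a correlation of 0.0878, against -0.137 to 0.108 for the others, too low to tell its sample. A swap with an array outside the series stays open.

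The second pattern is Hprt, which was higher with doxycycline in every pair of the 9 arrays. A different mix of the sorted cell types goes against its lowest value with doxycycline lying 0.55 above its highest untreated value in any fraction. A rise of the region on the X chromosome goes against the highest of its 20 neighbours, 0.31, with a median of 0.01 over the 742 measured genes on X. Many of these neighbours are microRNA genes, and whether the array reads them was not checked, so this rests on the others. Those lay between -0.31 (Plac1) and 0.31 (Gpc3), with Phf6 at -0.08 and Mospd1 at 0.05. In A2lox cells the doxycycline-responsive cassette lies next to Hprt, as background, so transcription running on from the cassette may raise Hprt; an action of Meis1 protein may too. The untreated CD41hi cells had more Meis1 than CD41int cells by 1.44 and more Hprt by 0.84, a ratio of 0.586 against 1.79 with doxycycline. These explanations cannot be told apart here, since no array has the cassette induced without Meis1.

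The third pattern is the lower level of erythroid and heme synthesis genes and the higher level of megakaryocyte genes with doxycycline in the 3 CD41-positive pairs. After the axis from CD41-positive to CD41-negative cells was removed, the mean over these pairs was left at -0.22 for erythroid (-0.33 before), -0.41 for heme synthesis and 0.31 for megakaryocyte genes, which goes against more CD41-negative cells as the whole cause. A part of it stays open, since pluripotency genes lay at 0.14 against 0.15 predicted by that axis, epithelial at 0.19 against 0.17 and stroma at 0.12 against 0.07, and since in CD41int cells the erythroid genes were left at -0.12, their upper quartile at 0.05. Across genes, the doxycycline difference also correlated with the untreated level, at r = -0.279 in day 7 CD41+ and -0.338 in CD41int cells. In CD41hi cells it was -0.117, and in day 8 CD41- cells -0.0516. This relation to level was not removed, so the match of these lists does not single out CD41-negative cells. Removing the axis from CD41hi to CD41int in the CD41hi pair left erythroid genes at -0.58 (-0.57 before), and in the CD41int pair a drift giving the erythroid -0.26 would take 0.9 of that axis, on which megakaryocyte genes lie at 2.22, against 0.12 measured with doxycycline, which goes against a drift of these gates for erythroid genes, while for megakaryocyte genes it stays open (0.28 left of 0.44 in CD41hi cells, or 0.25 with another slope, their lower quartile then at -0.0453). An action of Meis1, one of doxycycline itself and a difference between cultures stay open, as none was tested, and no list passed for doxycycline with an estimated correlation.

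The doxycycline difference of some lists differed between fractions or days on the 9 arrays, by camera on the interaction term. For CD41 the medians were 0.50 for epithelial, -0.30 for erythroid, -0.15 for heme synthesis, 0.18 for neural and 0.36 for pluripotency genes, and for day -0.29 for interferon genes, where CD41- and day 7 are each a single pair. With an estimated correlation 0 of these 6 passed, and adjusted p = 0.49 with an estimated correlation for the 5 CD41 lists and 0.993 for interferon. On 10 arrays 9 lists passed for CD41 and 6 for day, and 0 of these with an estimated correlation. Erythroid genes started lower in CD41- cells, at a mean of 6.25 on untreated day 8, which limits how far they could fall.

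Other assignments of treatment within pairs and of gate within cultures were counted. For doxycycline on 10 arrays all 16 assignments gave as many genes as the real one, 0, the highest other being 0, and on the 9 arrays 1 of 8 did, the real one with 1 gene, the highest other being 0. Both sets are too few for a share under 0.05. For CD41-positive against CD41-negative cells on 10 arrays 1 of 36 assignments gave as many genes as the real 190, the highest other being 12. That is the smallest share these assignments allow, 0.0278. The fractions are different cell populations sorted from 4 cultures and cannot be exchanged freely, so this count does not exclude chance. With 9 arrays 2 of 18 gave as many as the real 1470, too few assignments for a share under 0.05. The highest other, 1746, took untreated day 7 CD41+ and both CD41hi arrays as the negative fraction, and so points to the CD41hi gate as a structure of the samples.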

How the results depend on the processing

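The fits on 9 arrays and their alternatives were chosen after the data were seen, and all other settings were planned. The cause of a moved value was not tested unless it is named.

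The array of day 7 CD41- cells with doxycycline decided most counts, and on 10 arrays it moved the median difference of all genes to 0.10 for doxycycline and -0.27 for day, from 0.00 and -0.01 on the 9 arrays. For the doxycycline effect, with 0 genes called, array weights gave 26 (11 higher, 15 lower), day 7 pairs alone 1, CD41-positive pairs alone 3 and single pairs left out 0 to 1. On the 9 arrays 1 gene was called, with median centring 7, second quantile normalisation 1, genes above the median level 10, every probe 1, trend and robust fit 39, array weights 1, adjusted p under 0.10 4, 2-fold 1, culture as a random block 4, and without the day 8 CD41- pair 3. Without the pairing (no replicate block) 0 genes were called on 10 arrays and 0 on the 9, against 0 and 1 with it, so on the 9 arrays the call of Hprt was lost, and no other gene call for doxycycline changed.

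For CD41-positive against CD41-negative cells (190 genes, 42.1% higher), second quantile normalisation gave 66 (53.0% higher), genes above the median level 97 (67.0%), trend and robust fit 478, array weights 3488, adjusted p under 0.10 515, no culture block 470, doxycycline arrays alone 0, and single arrays left out 1 to 1470. Untreated arrays alone gave 249 (92 higher, 157 lower), while the doxycycline arrays include the array that stands apart. In the 9 arrays 1470 were called (31.4% higher), with centring 1379, quantile 1439, above median 1129, every probe 1448, trend 1432, weights 3252, 0.10 2302, 2-fold 627 and no block 2380. On those, leaving out untreated array 1 or 2 gave 530, untreated arrays 3, 4 and 5 117, 1398 and 1015, and doxycycline arrays 2, 3, 4 and 5 1470, 206, 1860 and 1154. Doxycycline array 2 is there the only array of its culture, so the 1470 without it was fixed by the design.

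For CD41hi against CD41int (7 genes), quantile gave 0, above median 1, every probe 54, trend 270, weights 2958, 0.10 121, no culture block 103, day 8 arrays alone 2477 and single arrays left out 0 to 2477. On the 9 arrays 2477 were called, with centring 2823, quantile 2312, above median 2934, every probe 2495, trend 3443, weights 2486, 0.10 3371, 2-fold 836 and no block 2545. Leaving out doxycycline array 2 then gave 2477, untreated or doxycycline array 3 3177, untreated arrays 4 and 5 1543 and 1660, and doxycycline arrays 4 and 5 1285 and 1416.

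For day 8 against day 7 (3 genes), centring gave 5, quantile 0, weights 0, 0.10 5, 9 arrays 100, and single arrays left out 0 to 17004. The interactions (0 genes each) stayed at 0 in all settings except with single arrays left out, where they gave 0 to 15160 for CD41 and 0 to 15493 for day. By construction the highest of these left the array that stands apart as the only one of its arm, without its own spread. Lists called for doxycycline (8) were 0 with an estimated correlation, 4 above the median level, 0 by fry and 7 to 11 with single pairs left out, and on the 9 arrays 11, 0 with an estimated correlation and 16 without the day 8 CD41- pair. Genes 2-fold one way in every pair were 0, 1 at 1.5-fold and 1 on the 9 arrays.

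Several named genes reversed. For doxycycline, quantile normalisation gave Tyrobp 0.55 and Myb 0.28, and single pairs left out gave Tyrobp -0.61 to 0.11, Myb -0.42 to 0.13 and Cd14 -0.54 to 0.0921. Tdo2, at -0.25 on 10 arrays and -0.51 to 0.59 with single pairs left out, was 0.58 with array weights, 0.53 in day 8 pairs, 0.65 in CD41-positive pairs and 0.59 on the 9 arrays. Subsets of 2 pairs, each holding the array that stands apart, reversed more. In day 7 pairs alone Hprt was -1.25, Meis1 -0.18, Gucy1b1 -0.11, Ptn -0.35, Ppox 0.18, Tyrobp 0.85, Hsd3b6 0.36, Car1 0.0376, Clec4n 0.76, Tnnt2 -0.27, Cd14 0.56 and Myb 0.31. In CD41-negative pairs alone Hprt was -1.46, Meis1 -0.25, Gucy1b1 -0.27, Ptn -0.28, Ppox 0.15, Tyrobp 0.77, Ccl9 0.0855, Hsd3b6 0.37, Car1 0.32, Clec4n 0.79, Kel 0.12, Hbq1b 0.0424, Tnnt2 -0.89, Cd14 0.78, Myb 0.52 and Ccl3 0.0709. For day, Actc1, Cnn1 and Tubb3 went to -1.49, -1.43 and -1.33 on the 9 arrays. With single arrays left out they reached 3.42, 1.99 and 2.39 at most, and Kif5c lay between -1.16 and 0.0983, the latter without untreated replicate 1.

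Lists reversed by the direction of camera, some with a median of the old sign. For doxycycline on the 9 arrays without the CD41int pair this was cell cycle, median 0.0314. For day on the 9 arrays it was epithelial at -0.0420 (-0.16 above the median level; -0.0420 to 1.64 with single arrays left out) and myeloid at -0.0587 (-0.0239; -1.25 to -0.0587). For the CD41 interaction it was kinase inhibitors and apoptosis at -0.0081 (0.0094; -0.0081 to 0.58) and cell cycle at -0.0496 (-0.0513; -0.0496 to 2.64). For the day interaction it was epithelial at -0.16 (-0.25; -0.16 to 1.62), myeloid at -0.0349 (-1.22 to -0.0349), pluripotency at -0.11 (-0.0939; -0.11 to 1.52) and stroma at -0.12 (-0.17; -0.12 to 1.46). Of all other values under the planned settings, 1302 for named genes kept their direction and side of the threshold, 283 became and 305 ceased to be past it, and for lists these were 1371, 43 and 178. Under the added settings they were 72, 41 and 0 for genes and 320, 46 and 94 for lists.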

Other observations

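The comparisons here were chosen after the data were seen. The interferon genes that were higher on day 8 in CD41- cells were also higher on day 8 in CD41-positive cells, although the gates differ between days. Relative to day 7 CD41+ cells of the same treatment, the median of the interferon list was higher by 2.35 in untreated CD41int cells (16 of 17 genes higher) and by 1.29 in untreated CD41hi cells (17 of 17). With doxycycline it was higher by 1.83 in CD41int (17 of 17) and by 0.98 in CD41hi cells (15 of 17). Ifit3 read 11.27 in untreated CD41int, 9.44 in untreated CD41hi and 5.48 in untreated day 7 CD41+ cells. Each value is a difference between single arrays, and day and culture are the same split.

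Probes that name several genes or none were not part of the comparisons. Of these 7894 probes limma called 0 for doxycycline on the 9 arrays, 88 for CD41-positive against CD41-negative cells and 277 for CD41hi against CD41int cells.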
